A study of Homo sapiens with 12 samples.

How the data were processed

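The series holds messenger RNA sequencing of HMEC-1 cells in 4 groups of 3 libraries: control (CT), oncostatin M (OSM), oncostatin M with PF9363 (PF9363) and oncostatin M with CBP300 (CBP300), all sampled after 48 h. Per the labels' protocols, stranded poly(A) libraries were sequenced as paired ends. The deposited table gives 1 value per gene and library in TPM, made by the authors. Per the submitters' processing notes, Trimmomatic 0.40, Bowtie2, RSEM 1.3.3 and the GRCh38 genome were used. The notes give neither the role of each tool nor the annotation release, the gene lengths or any filter. No reads were aligned again here.

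The table holds 60623 genes. Symbols were found for 99.5% of them in the name table, and 96.5% were in GENCODE release 29, from which gene types, positions, GC content and transcript length were taken. The TPM columns sum to 1e6 in 9 libraries. The 3 PF9363 columns fall short of it by 397, 430 and 178, for a reason that was not tested, and no correction was made for this. Ratios between low values showed that whole reads over a fixed length lie behind the table, and whole reads could be recovered in all libraries for 16841 of the 16848 tested genes (99.96%, tolerance 0.001). Depth was summed from these reads. In units of 1e6 reads it was 16.78, 17.19 and 19.56 in CT, 20.8, 16.75 and 15.74 in OSM, 16.51, 16.13 and 15.73 in PF9363, and 21.06, 73.25 and 13.41 in CBP300.

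Genes with at least 1 TPM in at least 3 libraries were tested (16848). Values were log2(TPM + 1), without further scaling. A linear model with 1 mean per group was fitted to the 12 libraries with limma 3.58.1 (R 4.3.3), with variances moderated along a trend on the mean. The 6 comparisons between groups were drawn from this fit, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. Genes with an adjusted p under 0.05 were called, and those with an absolute log2 change of at least 1 were also counted. The count of genes whose groups do not overlap was taken from the values themselves. For 35 gene lists fixed before the data were examined, limma's camera was run with an inter-gene correlation of 0.01 and adjusted over the lists of each comparison. Camera sets a list against all other tested genes. A list called higher or lower is so relative to them, and need not have risen or fallen itself. Member genes were counted from the genome-wide adjustment and from an adjustment over the list alone. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

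Genes named in the text followed a rule fixed in advance. For each comparison these were the 8 highest and 8 lowest log2 changes among called genes with at least 5 TPM in the higher group and no overlap, passing over clone names. Added were up to 4 called members per list, or up to 2 of the best expressed where fewer than 2 were called. The cytokine, its receptor chains, STAT3, SOCS3 and the acetyltransferases KAT6A, KAT6B, EP300 and CREBBP were always kept. So were the 4 genes with the largest oncostatin M change among those opposed in each direction by each inhibitor. Not all of them are printed. ICAM1 (4 comparisons of the inhibitors), IL6 (CBP300 with OSM) and VWF (CBP300 with CT) were added after their values were seen.

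A gene counted as opposed when it changed at least 2-fold in OSM versus CT and passed (adjusted p under 0.05) in the other direction between an inhibitor and OSM, by any amount. Because the OSM libraries enter both comparisons, 50 simulations without any inhibitor effect gave the covariance and the correlation due to the shared libraries alone. Each placed the residuals of the 12 libraries at random, with random signs, around group means in which both inhibitor groups equalled OSM. The numbers of overlapping genes were set against those of independent lists.

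The steps were tested on simulated data of 15460 genes with 200 changed genes (seed 11, dispersion 0.004931). For OSM versus CT 38 of 56 genes changed 1.5-fold, 76 of 89 changed 2-fold and 53 of 55 changed 4-fold were called in the right direction, and 10 of 15264 unchanged genes were called. Of 29 reversed 4-fold changes, 28 were counted as opposed, and 0 of 100 kept changes were. A raised list was called and 0 of 34 other lists were. The simulation held no trend on GC content and none between libraries of a group.

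Alternatives fixed in advance were pseudocounts of 0.1 and 5 TPM, no filter and a filter at 5 TPM, median-of-ratios and quantile scaling, removal of mitochondrially encoded genes, robust moderation, the replicate number as a block, a fit of only the compared groups, an estimated inter-gene correlation, ranks, cross-fitting over the OSM libraries and omission of each library in turn. A further 6 alternatives were chosen after seeing the data. They removed a smooth trend on GC content and transcript length (natural splines with 4 degrees of freedom for each, fitted to genes with a mean log2 value over 2 and applied to 16729 genes) from each library, did the same without CT replicate 1, removed the first axis of the deviations within groups, ran voom on the recovered reads, kept protein-coding genes only, or left out CT replicate 1 and PF9363 replicate 3. Replicate numbers were checked for pairing, and correlations of same-numbered libraries ran from -0.48 to 0.23, so no pairing was modelled in the main fit. No value column was left out. The raw reads were not used here.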

Results

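Messenger RNA was sequenced from HMEC-1 cells, an immortalised line of human dermal microvascular endothelium, in 4 groups of 3 libraries. Control cells (CT) received fresh medium. Cells of the other 3 groups received oncostatin M, a cytokine of the interleukin-6 family that signals through the shared receptor chain gp130, for 48 h. It was given alone (OSM group), with PF9363, which the labels call an inhibitor of the histone acetyltransferases KAT6A and KAT6B (PF9363 group), or with CBP300, which they call an inhibitor of the acetyltransferase EP300 (CBP300 group). The treatment protocol gives 10 ng/mL of oncostatin M, whereas the descriptions of single samples give 10 µg/mL, and the files do not settle which is right. The inhibitors were used at 30 µg/mL (PF9363) and 10 µg/mL (CBP300). No group had an inhibitor without oncostatin M and no vehicle is named, so each inhibitor was measured only in its presence. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries.

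The deposited values are TPM (transcripts scaled to a fixed total per library), and whole reads per gene could be recovered from them. In units of 1e6 reads, the libraries held 16.78 to 19.56 in CT, 15.74 to 20.8 in OSM, 15.73 to 16.51 in PF9363 and 13.41 to 73.25 in CBP300. Mitochondrially encoded RNA, one sign of RNA quality, took 14.4% ± 1.63 (SD, n = 3) of the TPM in CT, 17.6% ± 0.34 in OSM, 17.2% ± 1.44 in PF9363 and 17.9% ± 0.21 in CBP300. CT replicate 1 and PF9363 replicate 3 stood apart from their groups. CT replicate 1 differed from the other CT libraries by a mean of 0.58 and 0.48 (absolute log2) per gene, whereas those differed from each other by 0.22. PF9363 replicate 3 differed from the others of its group by 0.46 and 0.39, against 0.25 between them. The groups also differed in how the level of a gene depended on its GC content. Relative to the mean of the 12 libraries, the level changed per 10 points of GC content by 0.20 to 0.50 (log2) in CT, by -0.10 to 0.01 in OSM, by -0.11 to 0.12 in PF9363 and by -0.31 to -0.26 in CBP300. Per doubling of transcript length, fitted together with GC content, it changed by -0.16 to -0.05 in CT and by 0.03 to 0.04 in OSM. In PF9363 this was -0.08 to 0.01 and in CBP300 0.08 to 0.09. Values after removal of a smooth trend on GC content and transcript length, a correction chosen after seeing the data, are given as corrected values for part of the results.

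The comparison of OSM with CT asks what oncostatin M did to the cells. Camera called higher the lists of genes that answer to gp130 signalling (STAT3 targets), hypoxia and the acute phase. None of these 3 calls held with an estimated correlation. SOCS3, the feedback inhibitor of this receptor family (chromosome 17, 78356778 to 78360077, GRCh38), rose from 8.84 ± 3.08 to 382 ± 7.84 TPM (mean ± SD, n = 3 per group), a log2 change of 5.34 (SE 0.20, adjusted p = 2.13e-07). LIPG, which encodes endothelial lipase (chromosome 18, 49560699 to 49599182), rose from 0.669 ± 0.347 to 50.04 ± 4.19 TPM. LRG1, a secreted glycoprotein of the acute phase, rose from 2.08 ± 0.0810 to 69.1 ± 1.83 TPM. RNASE1, an extracellular ribonuclease made by endothelium (chromosome 14, 20801228 to 20803278), fell from 470 ± 61.0 to 71.9 ± 6.16 TPM.

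Of 20 measured STAT3 targets and feedback genes, 16 rose, 1 fell and 3 did not pass (adjusted over the list alone, 16 rose and 1 fell). BCL6, a transcriptional repressor, rose from 4.82 ± 1.82 to 55.9 ± 4.26 TPM, and CEBPD, a transcription factor of the acute phase, from 63.7 ± 3.66 to 416 ± 10.01 TPM. HIF1A, the hypoxia-inducible transcription factor, rose from 21.2 ± 16.1 to 190 ± 25.4 TPM, a log2 change of 3.46 that was 2.69 without CT replicate 1 and 4.04 without CT replicate 2. The list was called higher by camera (adjusted p = 0.000255; adjusted p = 0.766 with an estimated correlation). Of 22 hypoxia and glycolysis genes, 18 rose and none fell, with the same count adjusted over the list alone, and the list was called higher (adjusted p = 3.98e-06; adjusted p = 0.553 with an estimated correlation). SLC2A3, a glucose transporter, rose from 13.4 ± 2.15 to 122 ± 3.88 TPM, and HK2, a hexokinase, from 2.64 ± 1.08 to 20.04 ± 2.03 TPM. Of 9 acute phase and complement genes, 7 rose and none fell (8 rose adjusted over the list alone). This list was also called higher (adjusted p = 0.00111; adjusted p = 0.553 with an estimated correlation). C1R, a protease of the complement pathway, rose from 4.13 ± 0.255 to 60.7 ± 4.63 TPM.

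The receptor chains rose with their targets. OSMR, which binds oncostatin M, rose from 20.7 ± 5.98 to 141 ± 13.5 TPM. IL6ST, the gene of gp130, rose from 28.1 ± 20.2 to 197 ± 35.1 TPM, a log2 change of 3.10 that was 2.33 without CT replicate 1 and 3.64 without CT replicate 2. Its corrected change was 1.72. Of 12 genes for gp130-family receptors, cytokines and kinases, 7 rose and 2 fell, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.483). LIFR, the chain shared with leukemia inhibitory factor, rose by 1.39 (log2), but its corrected change was -0.03. The cytokine itself was at 0 TPM in 10 libraries and at 0.0959 and 0.0894 TPM in the other 2. Of the leukocyte adhesion molecules, ICAM1 rose from 24.9 ± 2.89 to 87.1 ± 1.48 TPM, while ICAM2, a constitutive one, fell from 111 ± 24.7 to 63.4 ± 4.82 TPM. That list of 9 went both ways, with 3 rising and 4 falling, the same adjusted over the list alone, and was not called (adjusted p = 0.629). In corrected values 1 rose and 6 fell (not called, adjusted p = 0.415). Among 16 chemokines and cytokines, 7 rose and 2 fell (7 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.758). In corrected values the balance turned, with 5 rising and 7 falling (not called, adjusted p = 0.724). CXCL2, which attracts neutrophils, rose from 2.71 ± 0.876 to 44.5 ± 2.72 TPM, and IL6 from 2.22 ± 0.591 to 10.4 ± 0.554 TPM. The targets of the inhibitors changed too, with KAT6A rising from 3.50 ± 0.756 to 12.98 ± 1.999 TPM and EP300 from 7.09 ± 3.06 to 29.3 ± 3.53 TPM. The corrected log2 changes were smaller, at 0.69 against 1.64 for KAT6A and 1.305 against 1.98 for EP300.

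Genes that fell included S100A6, a calcium-binding protein, from 5276 ± 1097 to 948 ± 33.1 TPM, and its relative S100A4 from 18.1 ± 6.41 to 2.57 ± 0.412 TPM. COL1A2, a chain of type I collagen, fell by 1.54 on the log2 scale. Of 22 cholesterol synthesis genes, 5 rose and 7 fell, with the same counts adjusted over the list alone (not called, adjusted p = 0.0734; adjusted p = 0.00858 without CT replicate 1), whereas 2 rose and 14 fell in corrected values (adjusted p = 0.0018). MVD, an enzyme of this pathway, fell from 65.5 ± 12.1 to 29.1 ± 2.12 TPM. Epithelial markers, kept to watch for other cells, were called lower with 0 rising and 3 falling of 6 (the same adjusted over the list alone; adjusted p = 0.0238; adjusted p = 0.832 with an estimated correlation). Among them KRT19 fell from 5.60 ± 1.05 to 2.13 ± 0.682 TPM (adjusted p = 0.0552 for the list without CT replicate 1), and the list was not called in corrected values (adjusted p = 0.457), with median-of-ratios scaling (adjusted p = 0.103), with voom on recovered reads (adjusted p = 0.0543) or with the within-group axis removed (adjusted p = 0.608).

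With limma, 7087 genes were higher and 2553 lower in OSM than in CT of 16848 tested (adjusted p under 0.05, Benjamini-Hochberg), of which 2989 and 416 changed at least 2-fold. The 2 groups did not overlap for 67.4% of genes, where chance gives 10% for a single gene, here and below. Genes moved together, so the share over all genes can lie far from 10% by chance. It was not computed for regrouped libraries. The median gene shifted by 0.31 (log2). All 57 genes named under this comparison changed beyond that shift in their own direction. Most were chosen for large changes, so this count was largely fixed by the choice and is no test. Relative to the shift, the change was 5.03 for SOCS3, 2.44 for OSMR and -3.00 for RNASE1. The division into higher and lower depended on scaling, at 5031 and 4694 with median-of-ratios factors and at 3948 and 4572 in corrected values, where 790 calls turned to the opposite call. With the within-group axis removed 3859 genes were higher, and 1707 genes were at least 2-fold higher without CT replicate 1. That axis held 47.9% of the variance within groups. Across genes it correlated at -0.76 with the OSM versus CT change. Along it, a response to the cytokine cannot be told apart from the way replicates of a group differ. Regrouping the same 6 libraries let camera call up to 10 lists, against 4 for the real groups.

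**Figure D1:**
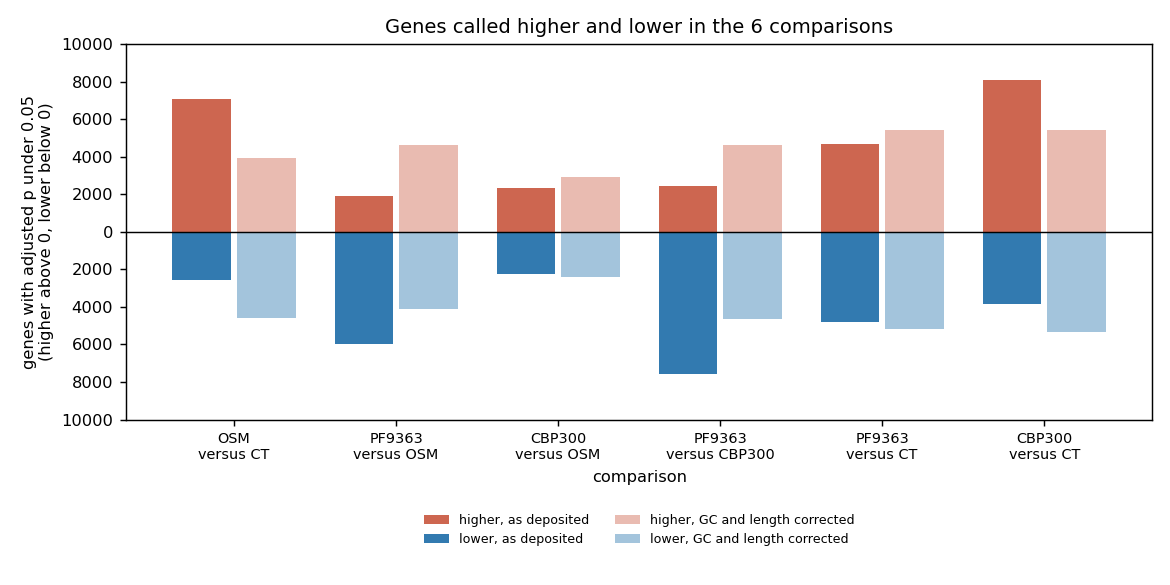
Genes called higher (above 0) and lower (below 0) by limma in each of the 6 comparisons, as deposited (dark bars) and after removal of trends on GC content and transcript length (pale bars). The deposited values gave 7087 higher and 2553 lower genes in OSM versus CT, and the corrected values 3948 and 4572.

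The comparison of PF9363 with OSM asks how cells given the KAT6A/B inhibitor with the cytokine differed from cells given the cytokine alone. All 3 PF9363 libraries, and no others, summed to under 1e6 TPM. Mitochondrial ribosomal RNA took 3.89% ± 0.18 of their TPM, against 1.79% ± 0.02 in OSM. The labels name no batch, so a technical difference of the whole group cannot be told apart from the inhibitor. Camera called the lists of interferon-stimulated and MHC class I genes higher, and those of matrix and HOX genes lower. Such calls are relative to the other tested genes, and the median tested gene fell by 0.31 (log2) here. Among these calls only that of the interferon list held with an estimated correlation. MX1, an antiviral GTPase (chromosome 21, 41420304 to 41459214), rose from 1.74 ± 0.321 to 19.2 ± 0.900 TPM (log2 change 2.88, SE 0.12, adjusted p = 1.11e-07). OAS2, a sensor of double-stranded RNA, rose from 3.79 ± 0.484 to 30.1 ± 4.59 TPM, and IRF7, a transcription factor of the interferon response, from 36.4 ± 2.77 to 157 ± 22.2 TPM. Of 34 measured interferon-stimulated genes, 22 rose and 3 fell, with the same counts adjusted over the list alone, and 28 rose and 1 fell in corrected values. The list was called higher (adjusted p = 9.44e-14), and the call held with an estimated correlation (adjusted p = 0.0465).

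Of 17 genes of MHC class I antigen presentation, 8 rose and none fell, with the same count adjusted over the list alone, and 16 rose in corrected values (adjusted p = 1.3e-05; adjusted p = 0.0639 with an estimated correlation). HLA-E rose from 625 ± 15.1 to 1268 ± 38.1 TPM, HLA-B from 418 ± 21.9 to 886 ± 121 TPM, and B2M, the shared light chain, from 692 ± 26.0 to 1252 ± 160 TPM. Of 17 NF-kappaB targets and feedback genes, 6 rose and 3 fell, the same adjusted over the list alone (called higher, adjusted p = 0.00452; adjusted p = 0.37 with an estimated correlation). The median log2 change of this list was 0.05, against -0.31 over all tested genes. CD40, a receptor for T cell help, rose from 2.39 ± 0.0385 to 17.6 ± 3.71 TPM. Of 16 chemokines and cytokines, 8 rose and 4 fell, the same adjusted over the list alone (called higher, adjusted p = 0.00452; adjusted p = 0.406 with an estimated correlation; adjusted p = 0.0548 in corrected values with CT replicate 1 left out). CXCL1 rose from 4.06 ± 0.863 to 17.7 ± 0.969 TPM, whereas IL6 fell from 10.4 ± 0.554 to 2.37 ± 0.676 TPM. ICAM1 fell from 87.1 ± 1.48 to 43.3 ± 3.80 TPM.

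Of 20 MYC target and ribosome biogenesis genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), and the call (adjusted p = 3.26e-05) held with an estimated correlation (adjusted p = 0.0465). NOP56, a component of the ribosomal RNA methylation complex, rose from 193 ± 2.97 to 375 ± 24.5 TPM. Of 23 G2/M genes, 8 rose and none fell, the same adjusted over the list alone, and 17 rose and none fell in corrected values. The list was called higher (adjusted p = 3.26e-05), but not with an estimated correlation (adjusted p = 0.494). AURKB, a mitotic kinase, rose from 241 ± 9.72 to 423 ± 44.7 TPM. Of 19 ATF4 and amino acid response genes, 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.000222; adjusted p = 0.37 with an estimated correlation), with the amino acid transporter subunit SLC3A2 going from 99.6 ± 3.05 to 294 ± 12.2 TPM. Of 23 S phase genes, 2 rose and 7 fell (2 and 6 adjusted over the list alone; not called, adjusted p = 0.621), against 10 and 4 in corrected values (called higher, adjusted p = 0.0444). The p53 targets, with 4 rising and 5 falling of 19 (the same adjusted over the list alone; adjusted p = 0.3), were not called either, nor with 8 rising and 4 falling in corrected values (adjusted p = 0.212). Of 15 genes of the unfolded protein response, 2 rose and 2 fell, the same adjusted over the list alone (not called, adjusted p = 0.115), against 9 and 1 in corrected values (called higher, adjusted p = 0.0354). Of 16 AP-1 and immediate early genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone). Camera called this list higher (adjusted p = 0.000114), but not with an estimated correlation (adjusted p = 0.406). Of 16 ERK feedback genes, 5 rose and 3 fell, the same adjusted over the list alone. That list, with a median log2 change of 0.25, was called higher (adjusted p = 0.0246), but not with an estimated correlation (adjusted p = 0.666) or without PF9363 replicate 1. The single genes with the steepest rises included PAEP, a secreted lipocalin, from 0.290 ± 0.253 to 46.5 ± 8.94 TPM, and NGFR, the low-affinity neurotrophin receptor, from 0.444 ± 0.168 to 32.6 ± 2.89 TPM.

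Of 27 basement membrane and matrix genes, 2 rose and 17 fell (3 and 17 adjusted over the list alone), with 4 and 14 in corrected values. The list was called lower (adjusted p = 0.0214; adjusted p = 0.715 with an estimated correlation). COL4A2, a chain of basement membrane collagen, fell from 103 ± 2.63 to 27.1 ± 3.48 TPM, and EFEMP1, a fibulin of the matrix, from 2230.0 ± 131 to 598 ± 86.5 TPM. Of 29 HOX genes, which set positional identity, 1 rose and 20 fell (1 and 21 adjusted over the list alone; called lower, adjusted p = 0.00561; adjusted p = 0.516 with an estimated correlation). HOXD9 fell from 83.9 ± 2.68 to 20.3 ± 2.24 TPM, whereas HOXD13 rose from 0.0467 ± 0.0809 to 2.90 ± 0.437 TPM. ING4, a subunit of a histone acetyltransferase complex, fell from 44.1 ± 1.99 to 13.01 ± 0.767 TPM. SV2A, a synaptic vesicle protein, fell from 40.7 ± 1.88 to 1.52 ± 0.368 TPM. Among endothelial identity genes the counts were 8 rising and 6 falling of 30 (8 and 7 adjusted over the list alone; not called, adjusted p = 0.0715), whereas in corrected values 15 rose and 4 fell and the list was called higher (adjusted p = 0.0277). NOS3, the endothelial nitric oxide synthase, rose from 8.57 ± 1.10 to 34.4 ± 5.98 TPM, and EMCN, a surface sialomucin, fell from 11.8 ± 0.443 to 0.543 ± 0.120 TPM. Some markers of other cells moved too. Of 15 leukocyte markers listed, only 2 reached the level needed for a test. Both rose, also adjusted over the list alone and in corrected values, and were too few for camera. Of 6 epithelial markers, 3 rose and 3 fell, with KRT18 going from 789 ± 38.4 to 3107 ± 623 TPM. Of fibroblast markers 2 rose and 1 fell of 5, of mural markers 2 rose and 4 fell of 7, and of lymphatic markers 2 rose and 3 fell of 5. The counts of these 4 lists were the same adjusted over the list alone, and none was called (adjusted p = 0.115, 0.109, 0.936 and 0.846). The inhibitor's target KAT6B fell from 4.16 ± 0.424 to 1.90 ± 0.762 TPM, and KAT6A stood at 12.98 ± 1.999 and 10.3 ± 4.44 TPM without passing (adjusted p = 0.275). SOCS3 stood at 382 ± 7.84 and 352 ± 51.9 TPM and did not pass (adjusted p = 0.628).

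With limma, 1901 genes were higher and 5993 lower in PF9363 than in OSM, of which 645 and 2195 changed at least 2-fold. The groups did not overlap for 59.9% of genes, where chance gives 10%. The median gene shifted by -0.31 (log2). The 76 passing genes named here all changed beyond that shift in their own direction, which their choice largely fixed. Relative to the shift the change was 3.19 for MX1 and -1.59 for COL4A2. The division depended on scaling, at 3711 higher and 3773 lower with median-of-ratios factors and 4631 and 4123 in corrected values. With the within-group axis removed 3965 were higher. On correction 3 calls turned to the opposite call.

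The comparison of CBP300 with OSM asks what the EP300 inhibitor changed in cells given the cytokine. Camera called the lists of endothelial identity, matrix, chemokine and acute phase genes lower and that of immediate early genes higher. None of these calls held with an estimated correlation. The immediate early list was also called higher in PF9363 versus OSM. EDN1, the vasoconstrictor peptide endothelin (chromosome 6, 12290363 to 12297194), fell from 155 ± 9.10 to 4.34 ± 0.446 TPM (log2 change -4.87, SE 0.30, adjusted p = 3.25e-06). MGP, an inhibitor of calcification in the matrix (chromosome 12, 14881181 to 14885926), fell from 27.5 ± 1.34 to 0.187 ± 0.0602 TPM. TAGLN, an actin-binding protein of smooth muscle, fell from 70.4 ± 5.81 to 4.22 ± 0.374 TPM.

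Of 30 endothelial identity genes, 1 rose and 22 fell (1 and 26 adjusted over the list alone; called lower, adjusted p = 2.09e-16; adjusted p = 0.102 with an estimated correlation). VWF, the von Willebrand factor, fell from 12.9 ± 0.304 to 0.826 ± 0.111 TPM. PLVAP, which forms the diaphragms of fenestrae, fell from 28.2 ± 1.73 to 3.25 ± 0.162 TPM. MMRN1, a multimerin of endothelium and platelets, fell from 14.6 ± 2.60 to 0.597 ± 0.05001 TPM. Of 24 genes of endothelial-to-mesenchymal transition, 1 rose and 14 fell (1 and 15 adjusted over the list alone; called lower, adjusted p = 3.2e-08; adjusted p = 0.238 with an estimated correlation), including FN1, fibronectin, from 755 ± 74.7 to 210 ± 13.2 TPM. All 5 fibroblast markers fell, also adjusted over the list alone (called lower, adjusted p = 7.19e-05; adjusted p = 0.102 with an estimated correlation), with COL1A1 going from 35.8 ± 2.16 to 8.23 ± 0.546 TPM. Of 6 epithelial markers, none rose and 4 fell, the same adjusted over the list alone (called lower, adjusted p = 0.00267; adjusted p = 0.238 with an estimated correlation; not called in corrected values, adjusted p = 0.0515). Of 7 mural markers, none rose and 3 fell, the same adjusted over the list alone (called lower, adjusted p = 0.0299; adjusted p = 0.24 with an estimated correlation). That call was lost in corrected values (adjusted p = 0.0515), without CBP300 replicate 3 (adjusted p = 0.0541), with ranks (adjusted p = 0.0599) and with the within-group axis removed (adjusted p = 0.0501). Of 5 lymphatic markers, none rose and 2 fell (0 and 3 adjusted over the list alone; called lower, adjusted p = 0.0432; adjusted p = 0.238 with an estimated correlation). The lymphatic call was lost without OSM replicate 1 (adjusted p = 0.0609), without OSM replicate 2 (adjusted p = 0.0546), without CBP300 replicate 2 (adjusted p = 0.0561) without CBP300 replicate 3 (adjusted p = 0.0503) and with the within-group axis removed (adjusted p = 0.0501). Of 27 basement membrane and matrix genes, 1 rose and 13 fell, the same adjusted over the list alone (called lower, adjusted p = 2.03e-05; adjusted p = 0.417 with an estimated correlation). BGN, the proteoglycan biglycan, fell from 1019 ± 75.4 to 164 ± 10.2 TPM.

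Further lists were called lower by camera. Of 34 interferon-stimulated genes, 2 rose and 9 fell (3 and 10 adjusted over the list alone). This call (adjusted p = 0.039) was lost with an estimated correlation (adjusted p = 0.392), with ranks and without OSM replicate 1. Of 17 genes of MHC class I presentation none rose and 5 fell, the same adjusted over the list alone. That call (adjusted p = 0.0133) was lost with an estimated correlation (adjusted p = 0.238) and in corrected values (adjusted p = 0.215). Of 16 chemokines and cytokines none rose and 12 fell, the same adjusted over the list alone (called lower, adjusted p = 2.67e-07; adjusted p = 0.102 with an estimated correlation). CXCL12, a chemokine that retains leukocytes and progenitor cells, fell from 59.8 ± 3.16 to 10.97 ± 0.566 TPM, CXCL2 from 44.5 ± 2.72 to 12.3 ± 1.39 TPM, and IL6 from 10.4 ± 0.554 to 3.96 ± 0.505 TPM. Of 9 acute phase and complement genes none rose and 8 fell, the same adjusted over the list alone (adjusted p = 2.67e-07; adjusted p = 0.102 with an estimated correlation), with C1R at 60.7 ± 4.63 against 25.1 ± 1.37 TPM. Of 23 angiogenic, tip cell and Notch genes, 4 rose and 10 fell (4 and 11 adjusted over the list alone; called lower, adjusted p = 0.0144; adjusted p = 0.511 with an estimated correlation; adjusted p = 0.0844 with ranks). PDGFB, which recruits pericytes, fell from 100 ± 3.38 to 11.1 ± 0.102 TPM and VEGFC, a lymphangiogenic factor, from 57.0 ± 2.14 to 12.6 ± 1.05 TPM. Of 29 HOX genes, 1 rose and 17 fell (1 and 21 adjusted over the list alone; called lower, adjusted p = 4.89e-12; adjusted p = 0.102 with an estimated correlation), including HOXD4, which fell by 1.65 on the log2 scale. Of 19 p53 targets none rose and 9 fell, the same adjusted over the list alone (called lower, adjusted p = 0.00267; adjusted p = 0.381 with an estimated correlation), with GDF15, a stress-induced cytokine, going from 92.4 ± 9.65 to 30.3 ± 1.55 TPM.

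Of 16 AP-1 and immediate early genes, 12 rose and none fell (13 adjusted over the list alone; called higher, adjusted p = 2.75e-06; adjusted p = 0.238 with an estimated correlation). FOS, an AP-1 subunit, rose from 8.10 ± 0.342 to 36.4 ± 0.706 TPM and KLF2, a flow-responsive transcription factor, from 76.7 ± 2.55 to 171 ± 7.27 TPM. Of 16 ERK feedback genes, 6 rose and 1 fell (9 and 2 adjusted over the list alone; called higher, adjusted p = 0.012; adjusted p = 0.558 with an estimated correlation). SPRY4, a feedback inhibitor of this pathway, rose from 1.86 ± 0.409 to 7.76 ± 0.503 TPM. MT1X, a metallothionein that binds zinc and copper, rose from 16.2 ± 2.71 to 96.4 ± 7.99 TPM. SOCS3 stood at 382 ± 7.84 and 450 ± 4.48 TPM without passing (adjusted p = 0.397), as did the inhibitor's target EP300 at 29.3 ± 3.53 and 52.3 ± 4.90 TPM (adjusted p = 0.131). EP300 passed without PF9363 replicate 3 (adjusted p = 0.0324), a library outside the comparison that enters the pooled spread.

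With limma, 2327 genes were higher and 2238 lower in CBP300 than in OSM, of which 486 and 617 changed at least 2-fold. The groups did not overlap for 66.5% of genes, where chance gives 10%, and the median shifted by 0.11 (log2). All 62 passing genes named here changed beyond that shift in their own direction, which their choice largely fixed. Relative to the shift the change was -4.98 for EDN1 and -3.04 for VWF. The count of higher genes hung on single libraries, at 4692 without CT replicate 1, 1105 without OSM replicate 2, 1090 without OSM replicate 3, 1152 without CBP300 replicate 1, 1101 without CBP300 replicate 2 and 1327 without CBP300 replicate 3. At least 2-fold higher were 306 without OSM replicate 3. Fitting only the 2 groups compared gave 6300 higher and 3770 lower genes, and removing the within-group axis 4441 and 4371. Of the calls among genes with a GC content up to 42.1%, 85.6% were higher, and of those from 56.1% upwards, 20.1%.

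**Figure D2:**
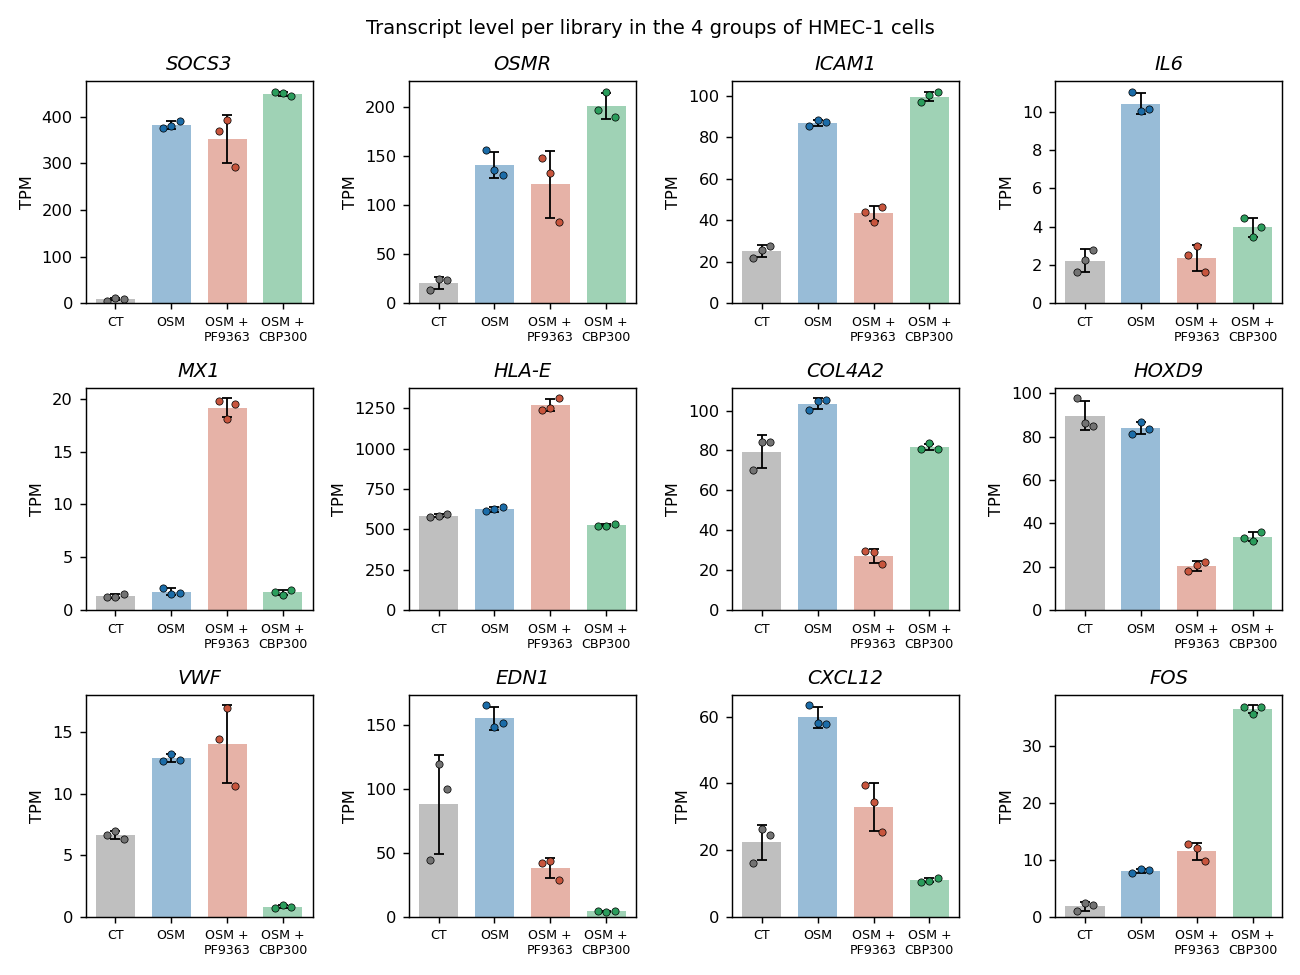
TPM (vertical axes, from 0) of 12 genes in the 4 groups; bars are means, error bars SD (n = 3) and points single libraries. SOCS3 was high in each group given oncostatin M, MX1 was highest with PF9363, and VWF and EDN1 were lowest with CBP300.

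How far each inhibitor opposed the oncostatin M response was measured on the genes that changed at least 2-fold in OSM versus CT and passed the other way, by any amount, with the inhibitor. Of the 2989 raised genes, 31% (928) fell with PF9363, against 1063.2 expected of independent lists, and 2.9% (86) rose further. Of the 416 lowered genes, 24.5% (102) rose with PF9363, against 46.9 expected. With CBP300, 7.2% (216) of the raised genes fell, against 397 expected, and 15.8% (472) rose further, while 6.5% (27) of the lowered genes rose, against 57.5 expected. Of the 416 lowered genes, 57 fell further with PF9363 and 95 with CBP300. For genes that changed further in the same direction no expected number was computed, so these counts cannot show a strengthened response. Over all 16848 tested genes, 1901 were higher and 5993 lower with PF9363, and 2327 and 2238 with CBP300. Genes raised by oncostatin M and lowered by CBP300 included LIPG, which went from 0.669 ± 0.347 in CT to 50.04 ± 4.19 in OSM and 4.75 ± 0.420 TPM in CBP300. CEACAM1, an adhesion molecule, went from 11.2 ± 2.997 to 152 ± 6.29 and then 25.9 ± 1.22 TPM. BCL6 went the same way with PF9363, from 4.82 ± 1.82 to 55.9 ± 4.26 and 18.4 ± 5.14 TPM. RNASE1, lowered by oncostatin M, stood at 470 ± 61.0 in CT, 71.9 ± 6.16 in OSM and 228 ± 27.9 TPM in PF9363. PI16, a peptidase inhibitor, went from 8.29 ± 0.434 to 0.682 ± 0.417 and 7.06 ± 0.371 TPM, and CLIC3, a chloride channel protein, from 15.7 ± 6.20 to 1.87 ± 0.805 and 16.6 ± 4.48 TPM.

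Because the OSM libraries enter both comparisons, 50 simulations with no inhibitor effect were run on the same libraries. The covariance of the changes across genes was -0.128 for PF9363 and 0.135 for CBP300, against -0.03 simulated for each, and the correlation -0.23 and 0.30, against -0.14. In corrected values, for which nothing was simulated, the covariance was -0.085 for PF9363 and 0.031 for CBP300, and the correlation -0.19 and 0.09. The slope of the CBP300 change on the OSM change, 0.17 as deposited, was -0.06 with the within-group axis removed. In corrected values 27.9% (254) of 911 raised genes fell with PF9363, now above the 224.5 expected, and 11.4% (104) rose further, while 32.7% (205) of 627 lowered genes rose, against 173.6 expected. With CBP300 17.9% (163) of the raised genes fell, above the 130.7 expected, and 14.4% (131) rose further, while 7.8% (49) of the lowered genes rose, against 109 expected. Of the 627 lowered genes, 55 fell further with PF9363 and 130 with CBP300. Again no expected number was computed for further changes. Over all 16729 corrected genes, 4631 were higher and 4123 lower with PF9363, and 2909 and 2401 with CBP300. The share lowered by PF9363 was 46% without CT replicate 1, 20.1% without PF9363 replicate 3 and 20.5% without OSM replicate 1. For CBP300 the shares were 12.8% and 11.8% without CT replicate 1. The inhibitors shared 451 higher genes (262.6 expected of independent lists, 1901 × 2327/16848) and 1232 lower genes (796.1 expected, 5993 × 2238/16848). A further 282 genes were higher with PF9363 and lower with CBP300, and 650 the reverse. The expected numbers take no account of the OSM libraries that enter both comparisons. The covariance was 0.068 against 0.036 simulated, and the correlation 0.16 against 0.51 simulated. The simulated correlation stems from the shared libraries alone, with no inhibitor effect to dilute it. It therefore cannot show how alike the inhibitors were.

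The direct comparison of PF9363 with CBP300 asks whether the inhibitors differed, at unequal doses and both with oncostatin M. Lists of interferon-stimulated, MHC class I, chemokine and endothelial identity genes were called higher with PF9363. Each of them was also called lower in CBP300 versus OSM, but the lists differed in where the change lay. The median log2 change of interferon-stimulated genes was 0.99 in PF9363 versus OSM and -0.07 in CBP300 versus OSM. For MHC class I genes the medians were 0.27 and -0.14. They were 0.39 and -1.01 for chemokines and cytokines, and 0.01 and -0.99 for endothelial identity genes. Of 34 interferon-stimulated genes, 28 were higher and 1 lower (29 and 1 adjusted over the list alone), and the call (adjusted p = 3.58e-17) held with an estimated correlation (adjusted p = 0.0236). Of 17 genes of MHC class I presentation, 12 were higher and none lower, the same adjusted over the list alone, and this call (adjusted p = 3.58e-08) also held with an estimated correlation (adjusted p = 0.0362). Of 30 endothelial identity genes, 20 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 6.33e-14; adjusted p = 0.0662 with an estimated correlation). VWF stood at 13.99 ± 3.18 TPM with PF9363 and 0.826 ± 0.111 TPM with CBP300, and NOS3 at 34.4 ± 5.98 and 3.44 ± 0.405 TPM. Some markers of other cells differed as well. All 5 fibroblast markers were higher, also adjusted over the list alone (adjusted p = 3.33e-05; adjusted p = 0.0662 with an estimated correlation). So were both measured leukocyte markers of the 15 listed, which were too few for camera. Of 6 epithelial markers, 3 were higher and 1 lower, the same adjusted over the list alone (called higher, adjusted p = 0.00467; adjusted p = 0.218 with an estimated correlation; not called in corrected values, adjusted p = 0.105, with median-of-ratios scaling, adjusted p = 0.05095, or with voom on recovered reads, adjusted p = 0.0565). Of 16 chemokines and cytokines, 14 were higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 1.15e-10; adjusted p = 0.0573 with an estimated correlation). CXCL8, which attracts neutrophils, stood at 12.1 ± 1.82 and 0.989 ± 0.332 TPM. Of 16 AP-1 and immediate early genes, 3 were higher and 8 lower (3 and 9 adjusted over the list alone; not called, adjusted p = 0.835). Among them EGR1, a transcription factor, was lower with PF9363, at 18.0 ± 4.49 against 180 ± 8.64 TPM, and so was ICAM1, at 43.3 ± 3.80 against 99.8 ± 2.39 TPM. With limma, 2450 genes were higher and 7592 lower with PF9363 around a median of -0.41 (log2), of which 939 and 3534 changed at least 2-fold, and the groups did not overlap for 71.1% of genes (chance 10%). The division was 4398 and 4706 with median-of-ratios factors and 4638 and 4665 in corrected values, where 292 calls turned to the opposite call, and 4252 were higher with the within-group axis removed.

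The comparisons of PF9363 and of CBP300 with CT ask how far treated cells stayed from control cells. SOCS3 stayed raised in both, at 352 ± 51.9 TPM with PF9363 and 450 ± 4.48 TPM with CBP300 against 8.84 ± 3.08 TPM in CT. Of 20 STAT3 targets and feedback genes, 17 were higher and 1 lower with PF9363 (17 and 2 adjusted over the list alone; adjusted p = 3.7e-06; adjusted p = 0.24 with an estimated correlation). With CBP300, 15 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0155; adjusted p = 0.619 with an estimated correlation). Of 34 interferon-stimulated genes, 30 were higher and none lower with PF9363 than in CT (30 and 1 adjusted over the list alone; adjusted p = 3.04e-10; adjusted p = 0.0565 with an estimated correlation). IFITM1, an antiviral membrane protein, stood at 52.98 ± 0.423 against 5.97 ± 1.80 TPM. Both measured leukocyte markers, of 15 listed, were higher with PF9363 than in CT as well. Higher and lower were 3 and 3 of 6 epithelial, 1 and 4 of 7 mural, 2 and 2 of 5 fibroblast and 2 and 2 of 5 lymphatic markers, with no call. All 5 counts were the same adjusted over the list alone. Of 30 endothelial identity genes, 4 were higher and 19 lower with CBP300 than in CT, the same adjusted over the list alone (adjusted p = 3.28e-07; adjusted p = 0.572 with an estimated correlation). ROBO4, a guidance receptor of endothelium, stood at 19.1 ± 1.13 against 143 ± 4.91 TPM, PLVAP at 3.25 ± 0.162 against 92.2 ± 8.001 TPM, and VWF at 0.826 ± 0.111 against 6.63 ± 0.344 TPM. Epithelial and fibroblast markers were also called lower with CBP300, but mural (0 higher and 3 lower of 7) and lymphatic (3 higher and 1 lower of 5) markers were not, with the same counts adjusted over each list alone. None of 6 epithelial markers was higher and 5 were lower, the same adjusted over the list alone (adjusted p = 0.00208; adjusted p = 0.572 with an estimated correlation; not called in corrected values, adjusted p = 0.0625, or with the within-group axis removed, adjusted p = 0.0551). Of 5 fibroblast markers, 1 was higher and 4 lower, the same adjusted over the list alone (called lower, adjusted p = 0.0411; adjusted p = 0.572 with an estimated correlation). The fibroblast call was lost without CT replicate 2 (adjusted p = 0.0559), without PF9363 replicate 1 (adjusted p = 0.0507) without PF9363 replicate 3 (adjusted p = 0.0538), with ranks (adjusted p = 0.112) and with the within-group axis removed (adjusted p = 0.0573). With limma, 4697 genes were higher and 4787 lower in PF9363 than in CT (2255 and 1851 at least 2-fold, median 0.04, no overlap for 53.4% of genes, chance 10%), and 1465 were at least 2-fold higher without CT replicate 1. Fitting only the 2 groups compared gave 2659 higher, and removing the within-group axis 7354 lower. In CBP300, 8099 were higher and 3825 lower than in CT (4797 and 1420 at least 2-fold, median 0.38, no overlap for 76% of genes, chance 10%). That division was 6045 and 5943 with median-of-ratios factors and 5434 and 5352 in corrected values, where 1547 calls turned to the opposite call (50 for PF9363 against CT). Regrouping the 6 libraries of CBP300 and CT let camera call up to 13 lists, against 10 for the real groups.

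**Figure D3:**
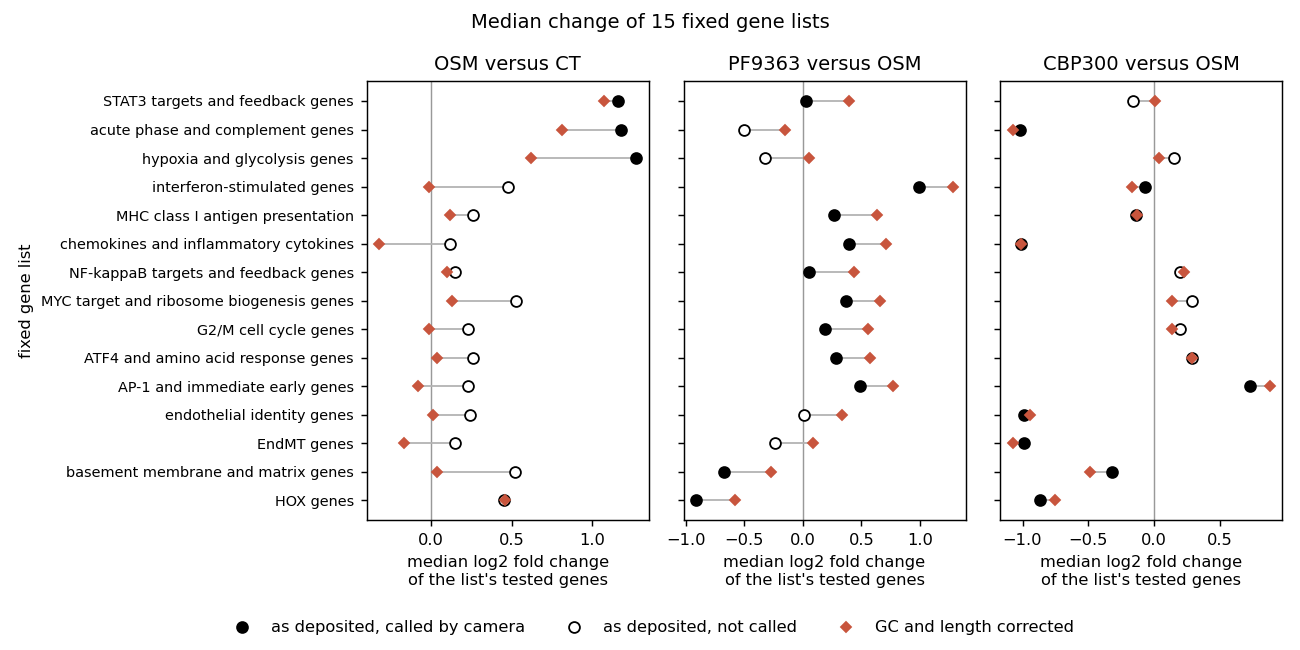
Median log2 fold change (horizontal axes) of the tested genes of 15 fixed lists in the comparisons of OSM with CT, PF9363 with OSM and CBP300 with OSM. Circles show deposited values, filled where camera called the list, and diamonds corrected values. Interferon-stimulated genes had a median of 0.99 in PF9363 versus OSM and endothelial identity genes one of -0.99 in CBP300 versus OSM.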

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

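The corrections for GC content and transcript length, the removal of the within-group axis, voom, the restriction to protein-coding genes and the joint omission of CT replicate 1 and PF9363 replicate 3 were chosen only after the data were seen. Alternatives set for a deposited table of counts (DESeq2, edgeR with RLE factors, filterByExpr) were not run, and of the count methods only voom was applied to the recovered reads. Of 20 results (gene counts of the 6 comparisons, the shares and slopes of opposition, and the list counts), those that could be computed stayed within 1.5 times their value and in their direction with a pseudocount of 5, no filter, a filter at 5 TPM, mitochondrial genes removed, robust moderation and protein-coding genes only. With the replicate block all 20 did, with 1748 genes higher in CBP300 versus OSM against 2327. For the others the values follow, and except where stated the cause was not tested.

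Scaling moved the division into higher and lower genes. With median-of-ratios factors 4694 genes were lower in OSM versus CT, 3711 higher and 3773 lower in PF9363 versus OSM, 4398 higher and 4706 lower in PF9363 versus CBP300, and 5943 lower in CBP300 versus CT. With quantile normalization the values were 4843, 3500 and 3908, 4286 and 4941, and 6101. With voom on recovered reads they were 4683, 3720 and 3746, 4569 and 4796, and 6133. The share of OSM-lowered genes raised by CBP300 was 2.9% with median-of-ratios factors. The share of OSM-raised genes lowered by CBP300 was 12% with quantile normalization and 11.9% with voom. The slope of the CBP300 change on the OSM change, 0.17 in the deposited values, was 0.06 with a pseudocount of 0.1.

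With GC content and transcript length corrected, 3948 genes were higher and 4572 lower in OSM versus CT, 4631 higher in PF9363 versus OSM, and 4638 higher and 4665 lower in PF9363 versus CBP300. CBP300 lowered 17.9% of OSM-raised genes, and its slope was 0.08. LIFR in OSM versus CT was at -0.03 (1.39 as deposited) and CREBBP in PF9363 versus OSM at 0.42 (-0.12). With the same correction and CT replicate 1 left out, 3492 were higher and 3987 lower in OSM versus CT, and 5250, 3935, 5303 and 5238 were higher in PF9363 versus OSM, CBP300 versus OSM, PF9363 versus CBP300 and CBP300 versus CT. PF9363 raised 46% of OSM-lowered genes, CBP300 lowered 26.6% and raised 13.3%, and the CBP300 slope was 0.04. LIFR was at -0.07, OSMR in PF9363 versus OSM at 0.18 (-0.25 as deposited) and CREBBP at 0.42.

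With the within-group axis removed, 3859 genes were higher in OSM versus CT, 3965 higher in PF9363 versus OSM, 4441 higher and 4371 lower in CBP300 versus OSM, 4252 higher in PF9363 versus CBP300 and 7354 lower in PF9363 versus CT. PF9363 lowered 52.6% of OSM-raised genes, CBP300 lowered 39.8% and raised 14.2%, and the CBP300 slope reversed to -0.06. IL6ST and CREBBP in PF9363 versus OSM were at 0.50 and 0.20, and IL6ST in CBP300 versus OSM at -0.34. The sign of the CBP300 slope therefore depends on this setting. The axis, signed to rise with GC content, correlated across genes with the change in each comparison. The correlation was -0.76 in OSM versus CT, -0.51 in PF9363 versus CT and -0.74 in CBP300 versus CT. It was 0.14 in PF9363 versus OSM, -0.39 in CBP300 versus OSM and 0.39 in PF9363 versus CBP300.

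Fitting only the 2 groups compared gave 6300 higher and 3770 lower genes in CBP300 versus OSM and 2659 higher in PF9363 versus CT, with CBP300 lowering 12.1% and raising 11.3%. This fit takes its variance from fewer libraries. Leaving out CT replicate 1 and PF9363 replicate 3 gave 2913 higher genes in PF9363 versus OSM and 6090 higher and 3686 lower in CBP300 versus OSM, with CBP300 lowering 14.8% and raising 14.3%. Cross-fitting gave PF9363 slopes of -0.15 and -0.12 (OSM replicate 2 and 3) and a CBP300 slope of 0.26 (OSM replicate 3), against -0.24 and 0.17.

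Leaving out each library in turn kept 14 of the 20 results within bounds. Genes higher in CBP300 versus OSM ran from 1090 without OSM replicate 3 to 4692 without CT replicate 1. The share of OSM-raised genes lowered by PF9363 ran from 20.1% without PF9363 replicate 3 to 46% without CT replicate 1, and the PF9363 slope from -0.33 without PF9363 replicate 1 to -0.11 without PF9363 replicate 3. For CBP300 the shares ran from 6.1% without OSM replicate 3 and 4.5% without CT replicate 2 to 12.8% and 11.8% without CT replicate 1, and the slope from 0.11 without CT replicate 1 to 0.18 without CT replicate 2.

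Camera called 56 lists higher and 27 lower over the 6 comparisons. With an estimated inter-gene correlation it called 4 higher and 0 lower. Of the 83 calls, 4 were kept in all 23 settings, 54 were lost only with the estimated correlation and 25 also elsewhere, and none turned.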

Other observations

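The genes in this part were chosen after their values were seen. In PF9363 versus OSM, 16 of 22 tested histone genes rose and 1 fell (17 and 0 in corrected values), and in CBP300 versus OSM 8 rose and none fell (13 and 0). With PF9363 H1-2, a linker histone, rose from 46.6 ± 2.53 to 443 ± 90.2 TPM (mean ± SD, n = 3) and H2BC12, a core histone, from 59.2 ± 2.44 to 438 ± 20.05 TPM. Of 10 MHC class II genes looked at 4 could be tested, of which 3 rose and 1 fell (3 and 0 in corrected values). CD74 rose from 0.641 ± 0.110 to 3.67 ± 0.146 TPM and HLA-DRA from 0.312 ± 0.163 to 10.07 ± 0.664 TPM, whereas HLA-DMA fell from 2.53 ± 0.824 to 1.45 ± 0.249 TPM. None of the 7 interferon genes looked at reached the level needed for a test. Mitochondrial ribosomal RNA took 3.89% ± 0.18 of the TPM with PF9363, against 1.52% ± 0.07 in CT and 1.79% ± 0.02 in OSM, and less than in CT in CBP300 (range 1.25% to 1.36%).

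Of 7 metallothioneins, which bind zinc, and the zinc exporter SLC30A1, none rose and 4 fell in PF9363 versus OSM, and 5 rose and none fell in CBP300 versus OSM. In corrected values 1 rose (SLC30A1) and 4 fell with PF9363, and 6 rose and none fell with CBP300. As deposited, only MT1E and MT2A passed in both comparisons. MT2A stood at 4647 ± 1863 TPM in CT, 2043 ± 213.7 in OSM, 915 ± 261 in PF9363 and 5194 ± 82.8 in CBP300. SLC30A1 rose from 25.5 ± 3.40 in OSM to 107 ± 2.73 TPM in CBP300.

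The tests of GC content, CT replicate 1, mitochondrial RNA, depth and red cell RNA below were chosen only after the results were seen, whereas the splits and the test for mislabelled libraries were set before. Each comparison has only 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many called genes in each comparison: 9640 in OSM versus CT (highest other 3), 7894 in PF9363 versus OSM (1), 4565 in CBP300 versus OSM (6), 10042 in PF9363 versus CBP300 (2), 9484 in PF9363 versus CT (4) and 11924 in CBP300 versus CT (1). For lists, 4 of 10 splits gave as many calls in OSM versus CT (real 4, highest other 10) and 4 of 10 in CBP300 versus CT (10 and 13). Only the real split did so in PF9363 versus OSM (16 and 13), CBP300 versus OSM (18 and 12), PF9363 versus CBP300 (20 and 19) and PF9363 versus CT (15 and 13). The same held for genes opposed by PF9363 (1030, highest other 0) and by CBP300 (243, highest other 3).

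The excess of higher calls in OSM versus CT (73.5% of calls) may stem from trends on GC content or transcript length between libraries. The share of higher calls differed by 54.3 points between the genes of lowest and highest GC content (96.3% and 42%). A first form of this test, the share after the trends were removed (46.3%), was dropped because the correction centres each library and so brings the share near an even division whatever the cause. CT replicate 1 as the only source was argued against, since the share stayed at 71.7% without it. Without mitochondrially encoded genes the share was 76.5%, but this could decide nothing. These genes took more of the TPM in OSM (17.65%) than in CT (14.38%), so removing them could only raise the share. A response of low-GC or long genes to the cytokine was not tested and stays open.

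CT replicate 1 and PF9363 replicate 3 stood apart from their groups. Mislabelled libraries were argued against, as the lowest median position over 6 pairs of library and other group was 0.76, where 1 is the own group and 0 the other, though this lies just over the bound of 0.75. Lower depth was argued against too. With all libraries thinned to the depth of the shallowest, each kept at least 96.3% of its excess distance from the others of its group over 10 draws. A first form of this test, the rank of the deeper library (6 shallower), was dropped because it left out PF9363 replicate 3, the second shallowest of the 12. Removing the trends on GC content and transcript length took away 39.5% of their squared deviation, between the bounds set for and against, so such trends and other causes cannot be told apart for these libraries.

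Reads of HBB, the beta globin gene, were found in CT replicate 2 (40.6 TPM) and OSM replicates 1 and 3 (48.8 and 132 TPM). They may come from RNA of red blood cells, since the lowest summed level of HBA1 and HBA2 there was 2.852 TPM, above 0.7615 TPM in the highest other CT or OSM library. In PF9363 the same source was argued against, as HBA1 and HBA2 summed to at least 56.47 TPM with a ratio of HBB to them of 0.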
